A study of Caenorhabditis elegans with 2 samples.

How the data were processed

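The data are ChIP-seq peak lists from whole Caenorhabditis elegans larvae at the L3 stage that carry a transgene coding for NHR-12, a member of the nuclear hormone receptor family, fused to eGFP. The labels describe 2 biological replicates of mixed sex, with a library size range of 150 to 350 bp, and both replicates form 1 group. No control immunoprecipitation or other condition was analysed here, so no comparison between conditions was made, and the antibody is given in the labels only by its target.

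The authors made 4 kinds of list for each of 2 genome builds, ce10 and ce11, per the text deposited with the samples. Each replicate has a list of candidate regions, called against control alignments and including background, which served as input to a reproducibility filter (the irreproducible discovery rate, IDR). A list pooled over both replicates and an optimal list of peaks past the IDR threshold complete the set. The aligner, the peak caller and the IDR threshold are not given in the sources used here. The signal value of a peak is a score that the authors' caller gave within its own list, and it was used only to describe and rank regions within that list. The q-value is deposited as −log10 and was converted back to q. Start, end and summit positions were used as the authors deposited them and are given 1-based. No list holds counts or coverage, so the read depth of the libraries is unknown, and the confidence intervals cover counting error over regions only.

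The ce11 lists were used throughout. The reference was the WBcel235 assembly, which is the same sequence as ce11, with the Ensembl 115 gene annotation and, for mitochondrial genes, the RefSeq annotation. All regions of the ce11 lists lay within their chromosomes (0 ended past a chromosome end). No coordinates were converted between builds. Peaks of the builds were matched by chromosome and by a signal value equal within 0.01.

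Candidate regions of both replicates, used as the background, were regions of replicate 1 whose summit lay inside a region of replicate 2 and that overlapped no optimal peak by 1 bp. There were 2929 of them, 502 on X and 2427 on autosomes. An optimal peak counted as found in a replicate when its summit lay inside one of the 1000 strongest regions of that replicate. Overlap between the strongest regions of the replicates was tested with 10000 random draws of ranks (one-sided), for which 0.0001 is the smallest p. The promoter share, the share of summits within 500 bp of the start of a protein-coding transcript, was compared with 100000 draws of background regions with the same number per chromosome (two-sided permutation test). It was computed on nuclear peaks, since no mitochondrial background region remained to draw from, and its alternative with the stronger peaks took the stronger 16 nuclear peaks. Gene lists, sequence words within 50 bp of summits and the share on X were compared by Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment over the 21 gene lists. Shares carry exact Clopper-Pearson intervals at the 95% level. Where a count of 0 is said to allow up to a share, that share is that of 3 counts. An upper 95% limit given for a count of 0 is the Clopper-Pearson limit. Peaks and genes are not independent replicates of worms, so these p-values describe the lists and not the spread between animals.

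The rule for named genes was fixed before the data were examined. Each optimal peak was assigned the protein-coding gene with the nearest transcript start up to 2 kb from the summit, a second gene if it was divergent and within 500 bp, and a non-coding gene within 500 bp. The rule named the genes of the 20 optimal peaks with the highest signal value, nhr-12 and the members of the 21 lists that had a peak. Since the 20 strongest peaks were all mitochondrial, genes of nuclear peaks are named in addition, and this was chosen after their values were seen.

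The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The same code was first tested on simulated data made of the real region positions with shuffled signal values. With 57 simulated peaks, 40 of 40 planted shared ranks were recovered, 20 of 20 planted X peaks were counted, and all 14 planted motifs at 20 X summits were found. The planted motifs were exact copies, counted without mismatches, so the search with up to 2 mismatches was not tested there. With random peaks, the overlap, promoter, half-site and X tests gave permutation or exact p = 1.0, 0.974, 0.516 and 0.861. In that random list, 5 mitochondrial peaks alone brought 13 tRNA genes and an adjusted p of 6.06e-06 for the tRNA list, because neighbouring tRNA genes share a peak. With nuclear peaks and genes only, 0 of 21 lists passed in that simulation.

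The alternatives tried were the ce10 lists, other rank limits, other definitions of overlap, windows and words, the stronger part of the peaks, other backgrounds and each replicate alone. Analyses restricted to nuclear peaks, and splits into X and autosomal peaks, were added after the data were seen.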

Results

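The deposited lists describe where DNA was enriched in chromatin precipitated with eGFP-tagged NHR-12 from L3 larvae. On ce11, the optimal list held 57 peaks with a median width of 396 bp. The pooled list held 217 regions, and the candidate lists held 13876 regions in replicate 1 and 23791 in replicate 2. The q-values of the optimal peaks ran from 0.0303 to 0.115, and 22 of the 57 were under 0.05. In replicate 1, 47 candidate regions had a q under 0.05, against 0 in replicate 2, where the lowest q was 0.0526. The read depth behind these lists is unknown.

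Mitochondrial DNA, which is 13794 bp long, held 25 of the 57 peaks (43.9%), and the X chromosome held 20 (35.1%). The other 12 lay on autosomes, with 4 on chromosome I, 3 on II, 1 on III, 3 on IV and 1 on V. The 20 peaks with the highest signal values were all mitochondrial. The strongest had its summit at position 4775 of mitochondrial DNA in CYTB, the gene of cytochrome b, with a signal value of 541. Next came peaks in ATP6, a subunit of ATP synthase (474), ND5, a subunit of respiratory complex I (435), and COX3, a subunit of cytochrome c oxidase (404). A peak at position 1139 in an rRNA gene had a signal value of 384, and peaks in ND1, ND3, ND4L, ND2 and ND4 had 370, 350, 304, 296 and 289. Peaks in COX1 and COX2 reached 204 and 168. Of the 25 mitochondrial peaks, 20 had their summit in a protein-coding gene, 3 in an rRNA gene, 1 in a tRNA gene and 1 in noncoding sequence. Together they covered 59.1% of mitochondrial DNA, whereas the nuclear peaks covered 0.013% of the nuclear genome. The candidate lists held 30 mitochondrial regions in replicate 1 and 23 in replicate 2.

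**Figure D1:**
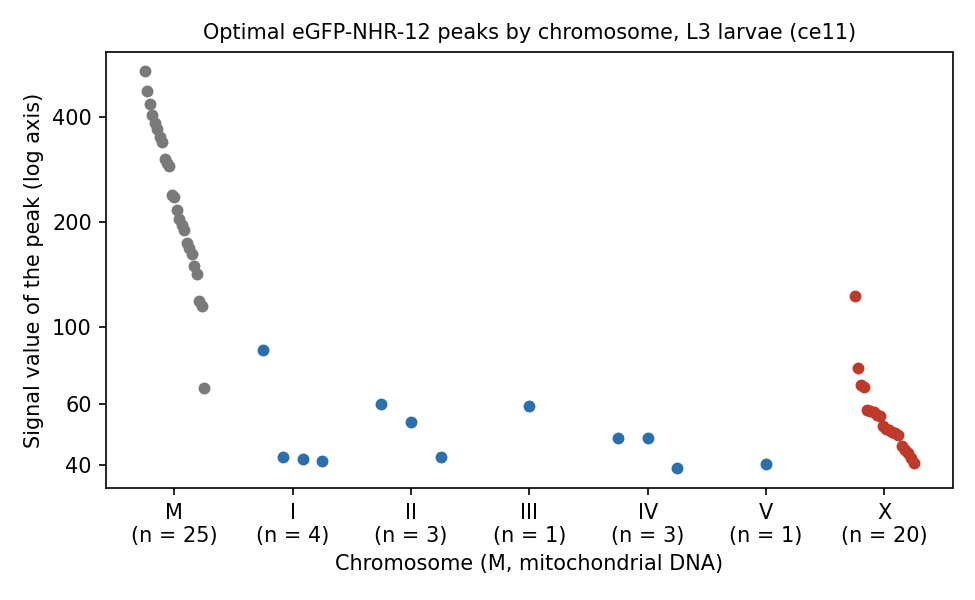
Signal value of each of the 57 optimal peaks (log axis) by chromosome, with the peaks of a chromosome ordered by signal value from left to right; each point is 1 peak of the list made from both replicates, so there is no error bar. The 25 mitochondrial peaks reach 541, and the strongest nuclear peak, on X, has a signal value of 123.

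**Figure D2:**
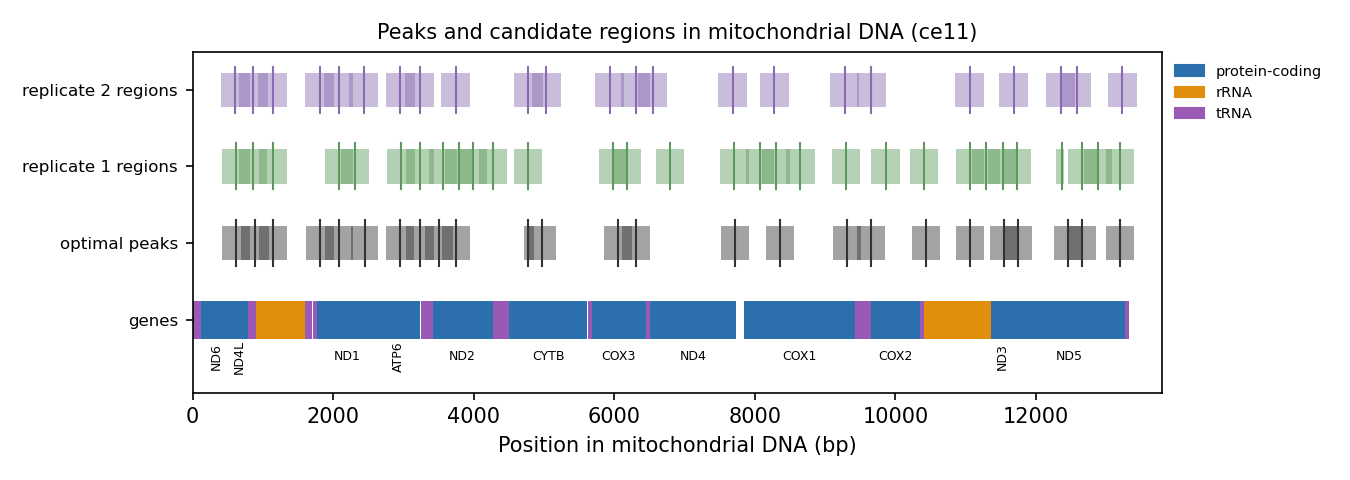
Mitochondrial DNA (position in bp) with annotated genes, the 25 optimal peaks and the candidate regions of each replicate (30 and 23); bars are regions, darker where they overlap, and vertical lines are summits. The optimal peaks cover 59.1% of the sequence.

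The 32 nuclear peaks had signal values from 39.2 to 123. The strongest lay between genes on X at 11094016 to 11094411, with its summit at 11094214, and ranked first among the nuclear regions of both replicates. The next (85.5) lay on chromosome I at 4172187 to 4172582, 70 bp from sls-2.4, an SL2 spliced leader RNA gene, and 796 bp upstream of egg-5. A peak inside sls-2.1, another SL2 RNA gene on chromosome II (summit 5844919), had a signal value of 59.9. A peak 351 bp upstream of rpl-3, which codes for a large-subunit ribosomal protein, on chromosome III (summit 3867503) had 59.2. Of the 18 annotated sls-2 genes, 2 had an optimal peak within 500 bp and 3 had a candidate region of both replicates only. On X, an intergenic peak at 13700869 had a signal value of 76.2, and peaks in introns of Y41G9A.17 and mom-1, which acts in Wnt secretion, had 68.1 and 67.3.

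The other autosomal peaks lay in or near annotated genes. On chromosome I, summits lay 197 bp upstream of nra-2 and 270 bp from the divergent start of lin-53, a histone-binding protein gene, 773 bp upstream of the proteasome gene pas-5 and 134 bp from the snoRNA gene F25H2.15, and in a coding exon of suro-1. On chromosome IV they lay 81 bp inside pigq-1, in a coding exon of Y43B11AR.3 at 278 bp from the snoRNA gene Y43B11AR.7, and in the 5′ UTR of Y43C5B.3. On chromosome II they lay in an intron of usp-39 and in the 3′ UTR of C17G10.6, and on chromosome V in the snoRNA gene C51F7.4. A gene start within 2 kb was present for 10 of the 12 autosomal peaks and for 9 of the 20 on X. X peaks near genes included those 471 bp upstream of ftt-2, a 14-3-3 protein gene, 622 bp upstream of the insulin-like gene ins-39, 740 bp upstream of nspc-17 and 985 bp upstream of fbxb-58. Of the 20 X summits, 14 were intergenic, 2 lay in introns, 2 in non-coding RNA genes, 1 in a tRNA gene and 1 in a coding exon, that of pks-1, a polyketide synthase gene.

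X held a larger share of the optimal peaks than of the candidate regions of both replicates: 20 of 57 (35.1%, 95% interval 22.9 to 48.9) against 502 of 2929 (17.1%; odds ratio 2.61, Fisher's exact test, two-sided, p = 0.00119). These sets are unlike, since 25 of the 57 peaks are mitochondrial and no candidate region of this background is. Among nuclear peaks alone, a restriction chosen after the data were seen, the share was 20 of 32 (62.5%, 43.7 to 78.9; odds ratio 8.06, Fisher's exact test, p = 1.67e-08). Among the 20 strongest nuclear regions, X held 11 in replicate 1 (55%) and 13 in replicate 2 (65%). Over all nuclear candidate regions its share was 18.3% and 17.7%, beside 17.7% of the nuclear sequence. The share over all chromosomes depends on replicate 2, since the 57 strongest regions of replicate 1 alone had 19.3% on X (Fisher's exact test, p = 0.724). It was 10.7% in the 28 strongest optimal peaks, of which 24 are mitochondrial. Among nuclear regions only, the strongest regions of replicate 1 had 39.3% on X (Fisher's exact test, p = 0.00545) and those of replicate 2 had 45.9% (p = 5.91e-05).

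Most optimal peaks were found in each replicate, while the lists diverged further down. Of the 57 peaks, 48 had their summit in one of the 1000 strongest regions of both replicates (84.2%, 72.1 to 92.5), and of the 32 nuclear peaks, 30 did. These peaks were selected by the authors for reproducibility, so the share is not a test. Of the 57 strongest regions of replicate 1, 35 overlapped one of the 57 strongest of replicate 2, against 0.176 with random ranks (permutation test, p = 0.0001, the smallest the draws allow). For nuclear regions the count was 18, and with regions ranked by q-value it was 21. Of the 1000 strongest regions, 93 overlapped, against 21.1 with random ranks (permutation test, p = 0.0001). Across the 2987 regions shared by the replicates, which are not independent, Spearman's correlation of the signal values was 0.10. The peak in suro-1 ranked 4 among nuclear regions in replicate 1 and 11886 in replicate 2, and the X peak at 13514554 ranked 1055 and 90. Of the 25 mitochondrial peaks, 22 had their summit in any region of replicate 1 and 23 in any of replicate 2. Strong peaks were among those whose summit lay in no region of replicate 1. Their summits were at 12458 in ND5 (signal value 435), 1813 in ND1 (370) and 9658 in COX2 (168). Regions of replicate 1 still overlapped each of these peaks. In replicate 2, no region held the summits at 3506 and 10433. A region of replicate 2 overlapped the peak at 3506, and none overlapped the peak at 10433.

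**Figure D3:**
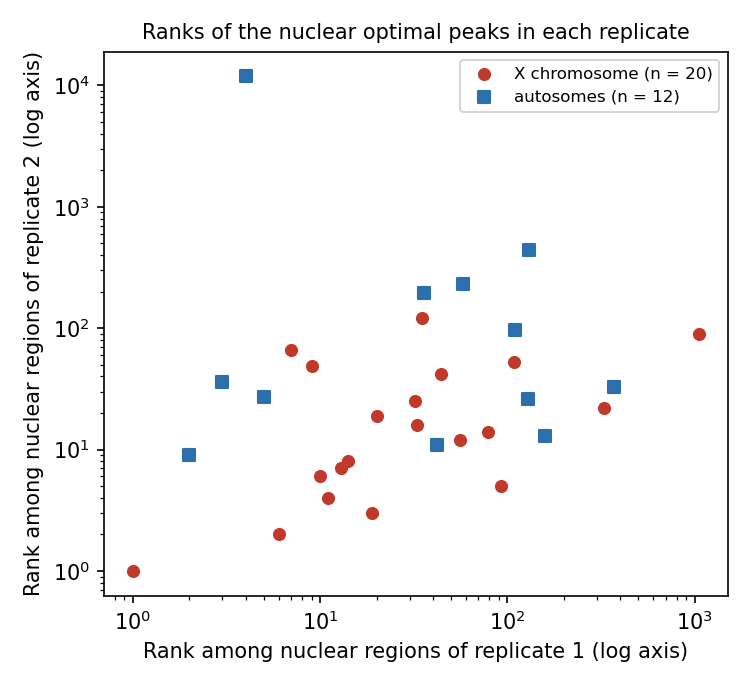
Rank of each of the 32 nuclear optimal peaks among the nuclear candidate regions of replicate 1 and replicate 2 (log axes; 1 is the strongest), with 20 peaks on X and 12 on autosomes. The peak in suro-1 stands apart at rank 4 in replicate 1 and 11886 in replicate 2.

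The share of nuclear peaks at promoters did not differ detectably from that of candidate regions. A summit within 500 bp of a protein-coding transcript start was present in 6 of 32 (18.8%, 7.21 to 36.4), among them the peaks at rpl-3, nra-2, pigq-1, ftt-2, Y43B11AR.3 and ZK1193.2, against 22.6% expected from candidate regions (permutation test, p = 0.783). The share was 2 of 20 on X and 4 of 12 on autosomes, a difference that did not pass Fisher's exact test (p = 0.165).

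Of the 21 gene lists, only the tRNA genes passed the threshold near optimal peaks, with 22 of the 82 in the background against 3.96 expected (Benjamini-Hochberg adjusted Fisher's exact p = 7.44e-12). Of those 22, 20 are mitochondrial. No mitochondrial candidate region remained outside the optimal peaks, so mitochondrial genes entered the background only by having a peak. That p therefore does not measure an over-representation of tRNA genes. With nuclear peaks and genes only, the tRNA list had 2 members with a peak against 1.01 expected (adjusted Fisher's exact p = 1.0), and 0 of the 21 lists passed. In that nuclear comparison the snoRNA genes came nearest, with 4 (C51F7.3, C51F7.4, F25H2.15 and Y43B11AR.7) against 0.651 expected (adjusted Fisher's exact p = 0.0617), followed by 2 snRNA genes, sls-2.1 and sls-2.4, against 0.26 (adjusted p = 0.273). The 4 snoRNA genes lay at 3 peaks, since C51F7.3 and C51F7.4 share 1. Among the nuclear part of the 57 strongest regions, the snoRNA count was 2 without replicate 1 (adjusted Fisher's exact p = 0.636) and 0 without replicate 2 (adjusted exact p = 1.0). The snRNA genes numbered 2 without replicate 1 (adjusted exact p = 0.543) and 3 without replicate 2, against 0.139 expected (adjusted exact p = 0.00478), the only list to pass in those 2 comparisons, which were chosen after the data were seen. Over all peaks the snoRNA and snRNA lists each had an adjusted p of 1.0. Ribosomal protein genes had 1 of 5 with a peak, rpl-3 (adjusted Fisher's exact p = 1.0). No peak lay near the 12 nuclear hormone receptor genes of the background. The count was also 0 for the 10 microRNA genes, the 9 detoxification enzymes, the 5 cuticle collagens, the 5 germline genes and the 5 lipid metabolism genes. It was 0 for the 4 neuronal genes, the 4 C-type lectins, the 3 seam, hypodermal and molting genes and the 2 genes each of the translation factors, histones, chaperones and muscle genes. The lists of homeobox, intestinal and proteasome genes had 1 gene each in the background and 0 with a peak, and that of the nuclear respiratory chain genes had 0 in the background. Adjusted p was 1.0 for each of these, and the small backgrounds leave little power.

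The sequence RGGTCA, the core recognition element of many nuclear receptors, lay within 50 bp of 4 of the 57 summits (7.02%, 1.95 to 17), against 4.27% of candidate regions (Fisher's exact test, p = 0.309). The 4 summits were those in mom-1, sls-2.1 and Y43B11AR.3 and the X summit at 7826009. The 57 include 25 mitochondrial summits, of which 0 had the sequence, whereas the candidate regions include no mitochondrial ones. Among nuclear peaks the share was 12.5% (Fisher's exact test, p = 0.0481), a single unadjusted test added after the data were seen. The second word, GAGAGA, lay at 5.26% of summits against 6.69% (Fisher's exact test, p = 1.0).

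The nhr-12 gene itself (WBGene00003611, chromosome V, 10082133 to 10084049, minus strand) is the target that the labels give for the strain's inserted transgene. The 40-kb window centred on it held 0 candidate regions in either replicate, where the median window held 5 in replicate 1 and 9 in replicate 2. The window stood at percentile 0.539 of 2503 windows in replicate 1 and 0.200 in replicate 2. No optimal or pooled region lay in it (0 of each).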

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

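Of 55 alternative values for the main results, 35 kept their direction and their side of the threshold or stayed near the main value, as did 19 of 23 for single gene lists. The direction turned in 8 of the 55 and in 3 of the 23, and 0 of those 11 alternatives passed the threshold. Alternatives restricted to nuclear peaks, to X or to autosomes were chosen after the data were seen. The ce10 list held 45 peaks in place of 57, and 44 of these had a ce11 peak of equal signal value. Of the 13 peaks in ce11 only, 5 were on X and 0 were mitochondrial. The others were autosomal, with 3 on chromosome I, 1 on II, 1 on III, 2 on IV and 1 on V. Most of the 12 autosomal peaks were thus in ce11 only, and the counts of genes near them were not repeated on ce10. Restricted to nuclear peaks, the share found in both replicates rose to 93.8%, the overlap of the 57 strongest regions fell to 18, the number of gene lists past the threshold fell from 1 to 0 because most of its tRNA genes are mitochondrial, and the RGGTCA share became 12.5% (Fisher's exact p = 0.0481). Ranking by q-value gave an overlap of 21 among the 57 strongest, and counting summits within 100 bp gave 53 among the 1000 strongest; the cause was not tested. The X share turned below that of the candidate regions, at 10.7% (Fisher's exact p = 0.459), in the 28 strongest peaks, of which 24 are mitochondrial and 3 are on X. With 1 replicate left out it ran from 19.3% to 29.8%. The promoter share passed the threshold under none of its 8 alternatives, but lay above its expected value at 1000 bp (43.8% against 38.4%), on autosomes (33.3% against 28%) and without replicate 1 (24.3% against 23.8%). Without replicate 2 it was 17.9% against 24.5%. The share of summits with the nuclear receptor element turned below that of candidate regions with RGKTCA (8.77% against 13.4%) and within 100 bp (8.77% against 8.91%). It also did so in the 28 strongest peaks (0 against 4.27%), of which 24 are mitochondrial. GAGAGA, a different word counted among these alternatives, lay below as well (5.26% against 6.69%). The snoRNA count turned to 0 in the 28 strongest peaks (1.34 expected) and without replicate 2, over all peaks and over nuclear peaks (1.64 and 0.347 expected). Around nhr-12 the percentile was 3.65 and 0.988 for 20-kb windows, 1.36 and 0.240 for 80-kb windows, and 16.4 and 16.1 with the 3000 strongest regions, in replicates 1 and 2. Taking the stronger part of the optimal list gives no peak count of its own. The lists carry no read depth, so its effect on the number of peaks could not be examined.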

Other observations

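Tests of the recruitment motif, of mitochondrial coverage, of X copy number, of the gap around nhr-12 and of non-coding genes near autosomal peaks were chosen only after the results were seen. Most X peaks shared a sequence. The 12-bp sequence TCGCGCAGGGAG, known from sites on X that recruit the dosage compensation complex, lay with at most 2 mismatches within 150 bp of 14 of 20 X summits (70.0%, 45.7 to 88.1). It did so at 1 of 502 X candidate regions (Fisher's exact test, p = 5.36e-22) and at 0 of 12 autosomal optimal peaks, which allows up to 25% (p = 0.000112 against X). The strongest nuclear peak, at X 11094214, and the peak in Y41G9A.17 held exact copies, and those in mom-1 and pks-1 and near nspc-17 had 1 mismatch. Peaks near ins-39 and fbxb-58 had 2, and the one near ftt-2 had 4. All 3 exact copies in the nuclear genome were on X and inside optimal peaks. A scan of all 32896 words of 8 bases within 100 bp of summits, which used no known motif, placed CGCAGGGA first among X peaks (12 of 20 against 1 of 502, one-sided Fisher's exact test, Bonferroni p = 7.06e-14), and 0 words passed on autosomes. Of the 16 words that passed on X, 5 lie inside the motif and 11 do not. Some of the 11 extend past the motif's end or differ from it by 1 base, such as ATCGCGCA (9 of 20) and CGAAGGGA (7 of 20). Others do not resemble it: TATCCACA was at 7 of 20 against 0 of 502 (exact Bonferroni p = 1.27e-06) and GTGGATAA at 7 of 20 against 5 of 502 (exact Bonferroni p = 0.000897). Read on opposite strands, these 2 words share a run of 7 bases, so they are not separate findings. Of the 7 peaks with each, 5 and 6 also held the motif, and what these words stand for was not tested. Across 200 shuffled versions of the motif, at most 2 X summits had a match.

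Autosomal peaks lay near small RNA genes more often than autosomal candidate regions did. A tRNA, snoRNA, snRNA, microRNA or rRNA gene lay within 500 bp of 5 of 12 autosomal summits (41.7%), against 2.88% of autosomal candidate regions (Fisher's exact test, p = 1.61e-05). All 5 lay near SL2 RNA genes or snoRNA genes. Control libraries were not analysed here, so enrichment of such genes in every library stays open. Among the 57 strongest regions the count was 5 of 20 autosomal summits without replicate 1 (exact p = 0.000272) and 4 of 17 without replicate 2 (exact p = 0.00158). On X it was 2 of 20 (exact p = 0.336 against X candidate regions), and the difference between X and autosomal peaks did not pass (p = 0.0735). With protein-coding transcript starts within 500 bp counted as well, it was 8 of 12 autosomal and 3 of 20 X summits. That difference passed (Fisher's exact test, p = 0.00601).

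For the X peaks, more X sequence in the ChIP libraries than in the control is argued against by the X share of all nuclear candidate regions, at most 18.3%. An excess that the control shared need not show in this share, and control reads were not analysed here. The 12 bases of the motif alone, on any chromosome, are argued against by autosomes: 0 of 37 genome matches with at most 1 mismatch lay inside a region of each replicate, optimal peaks included (upper 95% limit 9.49%), and 2 in each replicate's own list, against 11 of 27 X sites (40.7%, 22.4 to 61.2) with matches up to 1 kb apart joined. Joining was chosen after the data were seen, the 11 X sites are optimal peaks in which the motif was noticed and so describe the pattern only, and sequence around the motif was not tested. Among X sites outside optimal peaks, 0 lay in a region of each replicate. Autosomes held 0 exact copies against 3 on X, so the autosomal value covers copies with 1 mismatch only. A role of the chromosome itself is not shown by these values. A nuclear receptor core element within 50 bp, at 10% of X summits against 4.38% of X candidate regions (Fisher's exact p = 0.233), cannot be told apart from chance with 20 peaks. A candidate explanation, as a hypothesis found and tested on the same data, is that these X peaks are dosage compensation recruitment sites (motif at 70.0%); whether the tagged protein is bound there or such sites are enriched in any precipitation stays open, since none of another factor was analysed here.

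For the mitochondrial peaks, high coverage of mitochondrial DNA as a whole met its test, since the peaks cover 59.1% of it. That test cannot decide, because 25 peaks on 13794 bp cover much of the sequence whatever their cause. No biological explanation was tested. Enrichment at fixed positions within the circle also met its test: 17 of 30 summits of replicate 1 lay within 100 bp of one of replicate 2, more than in 99.1% of 13793 rotations of the circle (exact over all rotations, p = 0.00935). Shared positions could come from mappability or base content in every library, and control libraries were not analysed here. A link of the strongest peaks to non-coding RNA genes cannot be told apart from their being mitochondrial: 16 of the 20 lay within 500 bp of such a gene, but so does 75.1% of mitochondrial DNA.

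For the region around nhr-12, extra copies in the transgene that raise the ChIP libraries alone would put many candidate regions there, and the percentiles of 0.539 and 0.200 argue against this. The stretch without a candidate summit ran from 10042645 to 10103699 in replicate 1 (61.0 kb) and from 10042840 to 10109840 in replicate 2 (67.0 kb), beside median gaps of 4.87 and 2.81 kb. Only 11 of 13852 gaps were longer in replicate 1 and 3 of 23774 in replicate 2, at most 0.0794%. A candidate explanation is that the control library carried the same extra copies and raised the background there. It cannot be told apart from other causes, since the edges differed by up to 6.14 kb, over the 5 kb set for the test, and the control reads were not analysed here.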
